A study of Mus musculus with 2 samples.

How the data were processed

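CD31-enriched retinal cells of mice at postnatal day 6 were profiled with the 10x Genomics Chromium 3' v3.1 kit, per the labels' protocols, in 1 control and 1 Alk1 ECKO library. The deposited matrices hold raw UMI counts per gene and barcode, written by Cell Ranger 5.0.1 per the file headers, while the submitters' processing notes name Cell Ranger 6.1.1, FastQC 0.11.9 and the build mm10. Whether intronic reads were counted, which filter chose the barcodes and how many animals went into each library are not given in the sources used here. The files list 32285 genes, and the lowest total per barcode was 500 UMIs in both libraries. Gene positions were taken from GENCODE vM21 (mm10) by gene ID, which matched all 27 named genes.

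Cells with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs were kept, 7909 in control and 4237 in Alk1 ECKO. Scrublet (scanpy 1.11.5) was run per library. Its automatic threshold called 0 control and 1 Alk1 ECKO cell, so the cells with the highest scores were removed instead at a rate of 0.8% per 1000 cells, a choice made after this failure: 465 control (6.33%) and 143 Alk1 ECKO cells (3.39%). Both libraries were clustered together without batch correction on log-normalised counts of 3000 variable genes, without mitochondrial, ribosomal, haemoglobin and sex-linked genes, with 30 components, 15 exact neighbours (scikit-learn 1.9.0) and Leiden resolution 1.0 (leidenalg 0.10.2). A cluster took the name of the marker list with at least 3 genes among its top 20, ranked by CPM over the mean of the other clusters for genes above 50 CPM with 10 CPM added to both. Clusters with a median mitochondrial share under 1%, a median doublet score over 0.12 or at least 2 markers of another class among the top 10 genes were set aside. These naming and set-aside rules were written after the clusters had been seen. Endothelial cells were sub-clustered at resolution 0.6 into 10 sub-clusters.

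UMIs were summed over the cells of a class per library and expressed as CPM over all gene UMIs of that class (10352026 UMIs in control and 37743179 in Alk1 ECKO endothelial cells). Intervals at 95% are exact Poisson for a sum, exact conditional binomial for a ratio and Clopper-Pearson for a share, and cover counting error only. A ratio against 0 counts used a floor of 3 counts per library. No test was made across cells, since each genotype had 1 library. A gene was measured in a class with at least 30 UMIs over both libraries. The named genes are Acvrl1, Piezo1 and Cdh5, then the 12 highest and 12 lowest log2 ratios among 6180 eligible genes with at least 20 CPM in 1 library and 50 UMIs over both and an interval beyond 1.5-fold. Mitochondrial, ribosomal, haemoglobin, sex-linked and predicted genes and transcripts of other cell types were left out, as were 56 genes at over 5 times the endothelial CPM in another class of the library where they were higher. In other classes with at least 100 cells per library the 5 highest and 5 lowest genes were named. In each list the 3 members with the highest and the 3 with the lowest ratio, and any against the list's direction, could be named. Id2, Sema3g, Axin2, Mfsd2a, Slc7a1, Abcb1a, Cavin3, Ephb4, Piezo2, Esm1, Kcne3, Apln, Actb and Socs3 lie outside this rule and were chosen after their values were seen. One gene is not reported here. List medians are given for microglia or macrophages and mural cells as well, which lay below 100 cells in a library. The shares of cells and values within clusters were computed for genes chosen after their ratios had been seen, apart from Acvrl1 and Piezo1.

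A total of 35 gene lists with 809 entries, 802 of them in the files, were fixed before the data were examined. They cover SMAD target, BMP receptor, mechanosensitive, flow, VEGF receptor, tip cell, arterial, venous, barrier, fenestration, Wnt, Notch, YAP-TAZ, hypoxia, cycle, cycle inhibitor, inflammation, junction, matrix, integrin, mesenchymal, ligand, lipid, mural, microglial, glial, stress and sex-linked genes and transcripts of other cell types. Each list's median log2 ratio was set against 10000 random lists of the same size matched in 20 expression bins, as a description of these libraries, and its counting interval came from 500 Poisson draws. A member counted as higher or lower from 1.25-fold. These counts used ratios that were not set relative to the median of all measured genes, -0.21. A gene slightly below that median could thus count as lower, while a larger distance was needed to count as higher. The share of all measured genes beyond this fold is not given here. Ratios and intervals were tested on simulated counts drawn for the endothelial comparison (12499 genes, 200 of them changed in total, 50 per fold size). The simulated counts held Poisson error only, as the intervals assume, so this checks the calculation and not the spread between cells or libraries. Intervals covered the true ratio for 95.4% of the 12299 unchanged genes and excluded 1 for 4.63% of them. The right direction was called for 76.0% of genes at 1.5-fold, 92.0% at 2-fold, 100% at 3-fold and 98.0% at 5-fold.

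Alternatives fixed beforehand were a looser filter (500 UMIs, 300 genes, 20% mitochondrial), a stricter one (2000, 1000, 5%), doublets kept, an endothelial marker gate, TMM factors (edgeR 4.0.16 in R 4.3.3), a mean of per-cell CPM, thinning of each cell, cycling cells left out, equal sub-cluster makeup, free RNA subtracted and count minimums of 200 and 1. The depth of thinning (5000 UMIs, which left out 20 control and 260 Alk1 ECKO endothelial cells) and the minimum of 10 cells per library for equal makeup (met by 6 sub-clusters) were set after the data were seen. Equal makeup thus left out sub-clusters 0, 3, 5 and 7, with 257, 182, 128 and 69 of the 1170 Alk1 ECKO endothelial cells. The free-RNA share of endothelial UMIs was the median over 14 photoreceptor transcripts, 0.889% in control and 0.478% in Alk1 ECKO. It replaced a share from their sum, which Gngt2, expressed by endothelial cells, dominated. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the rest.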

Results

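Single-cell RNA sequencing was run on retinal cells of mouse pups at postnatal day 6 after enrichment with CD31 beads, which bind an endothelial surface protein. There was 1 library per genotype: a control (Alk1 f/f) and an endothelial knockout (Alk1 f/f with Cdh5-driven CreERT2, called Alk1 ECKO here). The control library held 8739 barcodes with 54800465 UMIs and a median of 3707 UMIs per barcode. The Alk1 ECKO library held 5308 barcodes with 62728605 UMIs and a median of 2564.5. After the cell filters and doublet removal, 7444 control and 4094 Alk1 ECKO cells were retained. There were no replicates, so every difference below is one between these 2 libraries, and each interval is a 95% interval that covers counting error only.

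The first comparison asked which cell classes each library held. Endothelial cells made up 4.11% of retained control cells (306 cells, 3.67 to 4.59) and 28.6% of retained Alk1 ECKO cells (1170 cells, 27 to 30). Mural cells, the pericytes and smooth muscle around vessels, were 0.148% (11 cells) in control and 3.62% (148 cells) in Alk1 ECKO, and microglia or macrophages were 0.699% (52 cells) and 4.71% (193 cells). Rods were lower in Alk1 ECKO, at 9.33% (382 cells) against 33.9% (2522 cells), as were Müller glia or late progenitors, at 4.62% (189 cells) against 9.22% (686 cells). Clusters that no marker list named held 2945 control and 363 Alk1 ECKO cells.

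Clusters with a median mitochondrial share below 1%, set aside from every class, held 34 control (0.457%) and 1432 Alk1 ECKO barcodes (35.0%). Of these, 7 control and 1285 Alk1 ECKO barcodes lay in 2 clusters matched to the endothelial class by marker number. The larger held as many erythroid as endothelial markers among its top genes (4 of each), and the smaller only 2 endothelial markers. Counting these as endothelial gave an Alk1 ECKO endothelial share of 60.0%, and leaving all low-mitochondrial clusters out of the retained cells gave 44.0%, with 4.13% in control. Intervals of shares are exact Clopper-Pearson intervals. The cells were enriched with beads and the yield of each class was not measured, so these shares do not measure the makeup of the retina.

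**Figure D1:**
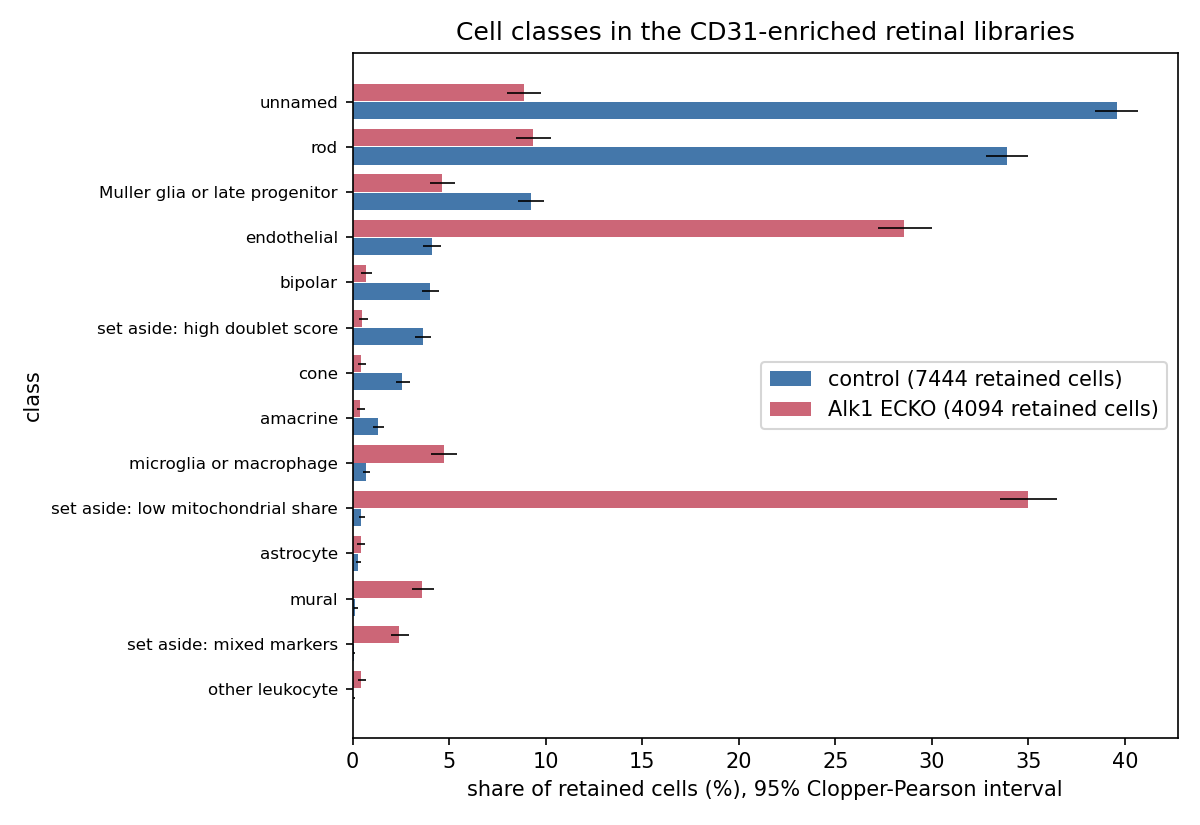
Share of retained cells per class (percent, horizontal axis) in the control library (7444 cells) and the Alk1 ECKO library (4094 cells), with exact 95% Clopper-Pearson intervals. Endothelial cells were 4.11% of the control and 28.6% of the Alk1 ECKO library.

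The main comparison asked how endothelial expression differed in the library labelled as an endothelial knockout of Alk1, a mouse model of hereditary hemorrhagic telangiectasia. Acvrl1 (ENSMUSG00000000530, chromosome 15, 101128522 to 101145336 in mm10), which encodes the BMP receptor ALK1, was at 115 CPM (109 to 122) in control and 118 CPM (115 to 122) in Alk1 ECKO endothelial cells, a log2 ratio of 0.04 (-0.05 to 0.13). The labels do not state which exons were deleted, and a 3' tag outside the deleted part checks neither the deletion nor the label. Piezo1 (ENSMUSG00000014444, chromosome 8, 122481698 to 122551329), the mechanically gated cation channel that the series title names as overexpressed, was lower in Alk1 ECKO, at 49.5 CPM (47.3 to 51.8) against 66.2 CPM (61.3 to 71.3), a log2 ratio of -0.42 (-0.54 to -0.29). These are RNA counts over all endothelial cells of 1 library per genotype. Protein was not measured here, so these counts do not test the statement of the title. After each cell was thinned to 5000 UMIs, 24.5% of control (19.6 to 29.9) and 21.4% of Alk1 ECKO endothelial cells (18.8 to 24.2) held a Piezo1 UMI, intervals that overlap. The same share in Müller glia or late progenitors was 0.620% in control and 2.00% in Alk1 ECKO, with median depths of 6047 and 5174 UMIs before thinning against 19537 and 18405 in endothelial cells. Relative to the median over all 12499 measured genes, which was -0.21, the Piezo1 ratio was -0.20 (-0.33 to -0.07) and the Acvrl1 ratio 0.25, and with the same makeup of sub-clusters in both libraries the Piezo1 ratio came to -0.05. Cdh5, which encodes VE-cadherin and whose promoter drove the recombinase, was at 770 CPM in control and 632 CPM in Alk1 ECKO (log2 ratio -0.29, -0.32 to -0.25). The Cdh5 ratio thus lay only slightly below the median over all measured genes, -0.21.

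Among the 12 genes with the highest ratios in Alk1 ECKO endothelial cells were Angpt2, a TIE2 ligand released by sprouting endothelium (106 against 23.9 CPM, log2 ratio 2.16, 1.97 to 2.35), Adm, the vasoactive peptide adrenomedullin (129 against 27.9 CPM, 2.20, 2.03 to 2.38), and Epor, the erythropoietin receptor (20.9 against 5.51 CPM, 1.92, 1.53 to 2.34). Fxyd6, a regulator of the sodium pump, had the highest ratio of the eligible genes (20.2 against 2.70 CPM, 2.90, 2.36 to 3.50), followed by Rarres1 (61.1 against 10.4 CPM, 2.55, 2.27 to 2.84). Rasgrp2, an activator of the small GTPase RAP1, was at 131 against 25.7 CPM (2.35, 2.17 to 2.53). Phlda3, a p53 target that restrains AKT, had a log2 ratio of 2.14, Prss23 2.13, the lipase Mgll 2.06 and Mall 1.94. The interferon-inducible GTPase Iigp1 was at 2.10, and at 1.62 without a sub-cluster of 182 Alk1 ECKO and 2 control cells rich in MHC class II transcripts. Hddc3 (2.47) was also higher in Müller glia or late progenitors (2.03) and rods (1.5) of the Alk1 ECKO library.

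The 12 genes with the lowest ratios included 3 transporter genes. Slco1c1, which carries thyroid hormone, was at 16.7 CPM in Alk1 ECKO against 121 CPM in control (log2 ratio -2.85, -2.99 to -2.71), Slc22a8, an organic anion transporter, at 6.52 against 20.7 CPM (-1.67, -1.94 to -1.39), and Slc7a8, an amino acid transporter, at 10.3 against 36.6 CPM (-1.82, -2.03 to -1.62). Spock2, a matrix proteoglycan, was at 148 against 601 CPM (-2.02, -2.08 to -1.97). The receptors Osmr (-1.89), Lepr (-1.77) and Epha4 (-1.80), the fatty acid elongase Elovl7 (-1.96) and Nxpe4 (-1.63) were lower too. Hspa1a, an inducible heat shock chaperone, was at 1.40 against 33.7 CPM (-4.59, -5.03 to -4.17). AY036118 (-2.29) and Eif3j2 (-2.56) were also lower in Müller glia or late progenitors (-2.82 and -1.72) and rods (-2.83 and -1.67). Of the other named genes, Fxyd6 (0.86) and Prss23 (0.77) were higher and Epha4 (-1.06) lower in Müller glia or late progenitors too, and Slc7a8 (-0.72) and Spock2 (-0.41) were lower in rods. Nxpe4 (0.90) and Phlda3 (-0.54) in Müller glia or late progenitors and Hspa1a (0.51) in rods went against their endothelial direction.

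**Figure D2:**
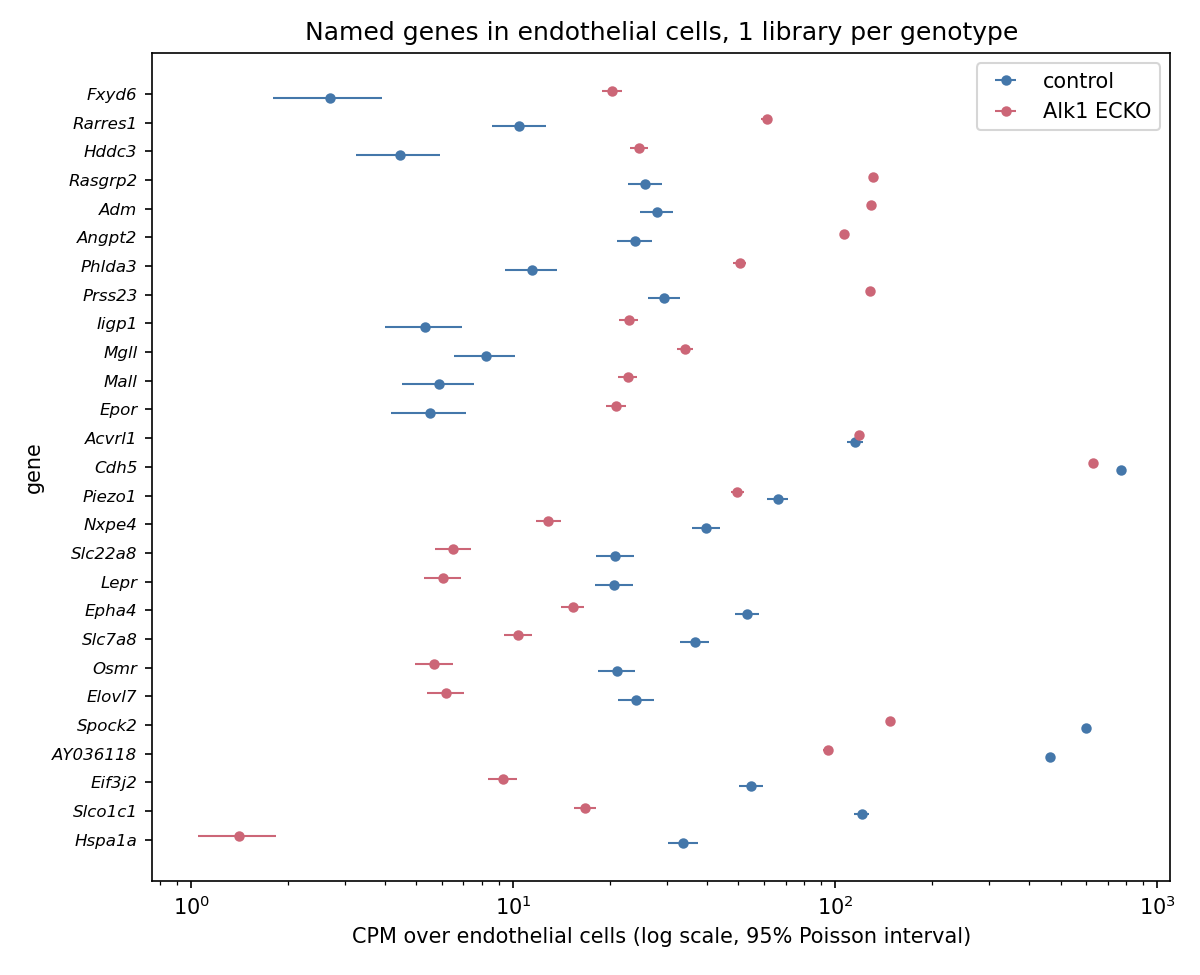
CPM over all endothelial cells (horizontal log axis) of the 3 genes fixed beforehand and the 12 highest and 12 lowest genes, in control and Alk1 ECKO, with 95% Poisson intervals. Slco1c1 was at 121 CPM in control and 16.7 CPM in Alk1 ECKO, and Angpt2 at 23.9 and 106 CPM.

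Genes of endothelial tip cells, the leading cells of vascular sprouts, were higher as a group in Alk1 ECKO. Of 26 measured members, 18 were higher and 0 lower by the fold size set for list members, with a median log2 ratio of 0.92 (0.69 to 1.07), above all 10000 matched random lists. Beside Angpt2 and Adm the higher members included Pgf, a VEGF family ligand (5.27 against 1.06 CPM, 2.31), Esm1, a secreted proteoglycan (182 against 52.9 CPM, 1.78), and Kcne3, a potassium channel subunit (163 against 46.6 CPM, 1.80). After thinning, 31.2% of Alk1 ECKO and 6.64% of control endothelial cells held an Esm1 UMI, against 1.0% and 0 of 484 cells in Müller glia or late progenitors. The tip cell collagen Col4a2 was slightly lower (-0.27). The tip cell median lay 1.14 above that of all genes, and 0.68 above it with the same makeup of sub-clusters in both libraries. The list was also higher in rods (4 of 9 higher, 2 lower, median 0.30, percentile 99.2), and in Müller glia or late progenitors its median was 0.17 (percentile 94.8).

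Genes of capillary transport and barrier function were lower as a group, with 22 of 27 measured members lower and 4 higher by that size. Their median log2 ratio was -0.77 (-0.87 to -0.69), or -0.56 relative to all genes, at percentile 0 of the random lists. Mfsd2a, the lipid transporter that restrains transcytosis in barrier endothelium, was at 88.0 against 232 CPM (-1.40), the cationic amino acid transporter Slc7a1 at 277 against 712 CPM (-1.36) and the efflux pump gene Abcb1a at 62.1 against 150 CPM (-1.28). Car4 (1.42), Slc1a1 (1.45) and Rgcc (0.82) went the other way. In Müller glia or late progenitors of the same libraries Mfsd2a (-2.01), Slc7a1 (-1.28) and the barrier list (9 of 17 lower, 3 higher, median -0.43, percentile 2.02) were lower too. Only 4.52% of 686 control and 1.06% of 189 Alk1 ECKO cells of that class held a Mfsd2a UMI, so its ratio rests on few cells. Of 22 Wnt and norrin response genes, 17 were lower and 0 higher (median -0.55, -0.64 to -0.46, percentile 0), among them the negative regulators Apcdd1 (116 against 256 CPM, -1.15) and Axin2 (13.8 against 27.6 CPM, -1.01) and the receptor Tnfrsf19 (-1.40). Apcdd1 (-0.52), Axin2 (-1.14) and Tnfrsf19 (-0.70) were also lower in Müller glia or late progenitors, where the Wnt list (10 of 17 lower, median -0.43) lay at percentile 26.4 of random lists. Sub-cluster 4, led by Spock2, Lrp8 and Slco1c1, held 148 of 306 control but 29 of 1170 Alk1 ECKO endothelial cells, and sub-clusters 0 and 5, led by Apod, held 5 and 3 control against 257 and 128 Alk1 ECKO cells. When both libraries were given the same makeup of sub-clusters, the medians relative to all genes came to -0.16 for the barrier and -0.06 for the Wnt list. This makeup left out sub-clusters 0, 3, 5 and 7, which had too few control cells, so these values do not cover most Alk1 ECKO endothelial cells.

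Venous genes were lower, with 13 of 20 lower and 5 higher (median -0.57, -0.63 to -0.48, percentile 0.01 of random lists). They included Nr2f2, the transcription factor of venous identity (34.0 against 71.3 CPM, -1.07), and Ephb4, the venous ephrin receptor (32.3 against 62.4 CPM, -0.95), while Emcn was higher (0.65). The arterial list had a median of 0.00 with 5 of 25 members higher and 7 lower (percentile 93.7). Within it Cxcl12 (-1.04), Htra1 (-1.44) and Bmx (-0.77) were lower, and Mgp, an inhibitor of BMP signalling and calcification, was higher (51.2 against 9.66 CPM, 2.40). Without the MHC class II sub-cluster Mgp was at 15.2 CPM in Alk1 ECKO (0.66, 0.35 to 0.98) and Bmx at -1.73. The arterial list lay 0.22 above all genes, and at -0.04 without the MHC class II sub-cluster and -0.51 without cycling cells. Of 14 fenestration, permeability and vesicle genes, 8 were higher and 3 lower (median 0.40, 0.34 to 0.46, percentile 100), with the caveolar genes Cav2 (126 against 60.5 CPM, 1.06) and Cavin3 (0.56) higher and Plvap, the diaphragm protein of fenestrae, lower (156 against 210 CPM, -0.43). That list lay 0.62 above all genes, and 0.30 above them without cycling cells.

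Direct targets of ALK1-SMAD1/5 signalling did not stand apart from other genes as a group over all endothelial cells (median -0.24, -0.34 to -0.17, percentile 12.6), with 2 of 18 members higher and 8 lower. This depended on the processing. Relative to all genes their median was -0.03, but -0.21 without the MHC class II sub-cluster. It ranged from -0.33 without cycling cells to 0.19 with the mean of per-cell CPM. Id3, a transcriptional inhibitor induced by BMP signals, was at 340 CPM in Alk1 ECKO against 720 CPM in control (-1.08, -1.12 to -1.04), and at -0.06 in Müller glia or late progenitors and 0.16 in rods. Id2 (-0.62) and Sema3g (-0.70) were lower as well, and the inhibitory SMAD gene Smad6 was higher (15 against 7.63 CPM, 0.97). Among 14 BMP and TGF-beta receptor and transducer genes, 9 were lower and 1 higher (median -0.36, percentile 4.81). Relative to all genes the median was -0.15, and 0.019 with the same makeup of sub-clusters in both libraries. The list held Bmpr2, the type II partner of ALK1, at 162 against 277 CPM (-0.77), and Smad1, which was higher (0.79). The BMP receptor list was as low in Müller glia or late progenitors (-0.44, percentile 1.67) and rods (-0.52, percentile 0.75), where Bmpr2 was at -0.45 and -0.74. Of 19 mechanosensitive channel and receptor genes, 7 were lower and 2 higher (median -0.25, -0.31 to -0.05, percentile 21.7). Trpm7 (-0.79) and Pkd2 (-0.67) were lower, as they were in Müller glia or late progenitors (-0.57 and -1.03) and rods (-0.63 and -0.80). The volume-regulated channel gene Lrrc8a was higher (0.55), and Piezo2 was at 124 against 118 CPM (0.07, -0.02 to 0.16).

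Flow and KLF response genes went both ways, with 5 of 25 higher and 6 lower (median -0.16, percentile 20.6). Klf2, a transcription factor induced by shear stress, was higher (484 against 236 CPM, 1.04), as it was in Müller glia or late progenitors (1.21) and rods (3.26), while Tek, which encodes the angiopoietin receptor TIE2, was lower (61.1 against 177 CPM, -1.54, -1.63 to -1.45). A Klf2 UMI was held by only 3.21% of 686 control and 7.41% of 189 Alk1 ECKO Müller glia or late progenitors. The rod class held 9952238 UMIs in control and 1035362 in Alk1 ECKO, and no interval is given for its Klf2 ratio. In the list of VEGF receptor, PI3K and AKT signalling, 15 of 29 genes were lower and 1 higher (median -0.33, percentile 2.58), among them the phosphatase gene Ptprb (-0.80), Pik3r3 (-0.74) and Rictor (-0.72), with the translation repressor Eif4ebp1 higher (0.86). In Müller glia or late progenitors and rods Pik3r3 (-1.32 and -0.90) and Rictor (-0.58 and -0.63) were lower and Eif4ebp1 (0.57 and 1.04) higher as well. Of 20 Notch genes 10 were lower and 3 higher (median -0.32, percentile 8.07), with Nrarp higher (0.68). Hes5 was at 1.38 against 21.2 CPM (-3.94), but it marks a cluster of Müller glia or late progenitors, where it was at -0.30, and transcripts of such cells in the endothelial class were lower in Alk1 ECKO. The G1/S list had 19 of 38 genes lower and 0 higher (median -0.33, percentile 4.43), and the G2/M list 15 of 44 lower and 4 higher (median -0.23, percentile 14.0), where Mki67 was lower (-0.83) and Ube2c higher (0.67). Relative to all genes the medians were 0.05 for flow and KLF response, -0.03 for SMAD target, -0.03 for mechanosensitive, -0.12 for VEGF receptor, -0.11 for Notch, -0.11 for G1/S and -0.01 for G2/M genes. Their directions depended on the scaling or on which cells were counted. The numbers of higher and lower members are not relative to all genes, whose median of -0.21 favours lower calls.

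Hypoxia and glycolysis genes were higher in Alk1 ECKO endothelial cells (10 of 36 higher, 4 lower, median 0.17, 0.12 to 0.23, percentile 99.7), and also in other classes of that library. Relative to all genes the endothelial median was 0.38, and 0.17 with the same makeup of sub-clusters in both libraries. The median log2 ratio was 0.45 (21 of 36 higher) in Müller glia or late progenitors, 0.62 (21 of 28) in rods and 0.50 (17 of 30) in mural cells. Egln3, an oxygen sensor, was at 2.19 and Ankrd37 at 1.40 in endothelial cells, and Ankrd37 at 1.37 in Müller glia or late progenitors and 1.62 in rods. In the dissociation and heat shock list (12 of 25 higher, 4 lower, median 0.19, percentile 99.3), the immediate early genes Fos (1.30) and Fosb (1.39) were higher and the chaperone genes Hspa1b (-5.69) and Hsph1 (-1.23) lower.

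Transcripts of other cell types within the endothelial class differed between the libraries by more than most endothelial lists. Photoreceptor transcripts had a median log2 ratio of -3.03 (13 of 14 lower) and glial and progenitor transcripts of -2.56 (6 of 6 lower). Mural transcripts (2.18, 1.84 to 2.86, 7 of 7 higher), microglial transcripts (2.11, 1.65 to 2.57, 7 of 8 higher) and erythroid transcripts (1.19, 0.53 to 1.32, 4 of 5 higher) were higher in Alk1 ECKO. The mural and microglial values rest on few control UMIs. Without the MHC class II sub-cluster, the mural gene Abcc9 held 7 in control, and the microglial genes C1qb and Fcer1g 7 and 4. Relative to all genes the direction turned without cycling cells, to -0.52 for mural and -1.39 for erythroid transcripts. After free RNA was subtracted, microglial and photoreceptor transcripts were both at -1.67. That value comes from the floor used where no counts are left in either library, so it shows no direction. The endothelial class included sub-cluster 7 (3 control and 69 Alk1 ECKO cells), led by the mural markers Higd1b and Rgs5, and without it the mural median relative to all genes was 2.28 against 2.40. The sex-linked list had a median of -0.29 with 1 of 6 members higher and 3 lower. Its X-linked members Xist (112 against 309 CPM, -1.46) and Tsix (-2.24) were lower. Of its Y-linked members only Eif2s3y (0.56) was higher by the fold size set for list members. Ddx3y (0.27) lay short of it, and the remaining lower member was Y-linked too. Xist was lower in Müller glia or late progenitors (-1.10) and rods (-1.30) of that library as well. The labels do not state the sex of the animals, so a difference in sex makeup between the libraries cannot be separated from the genotype.

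**Figure D3:**
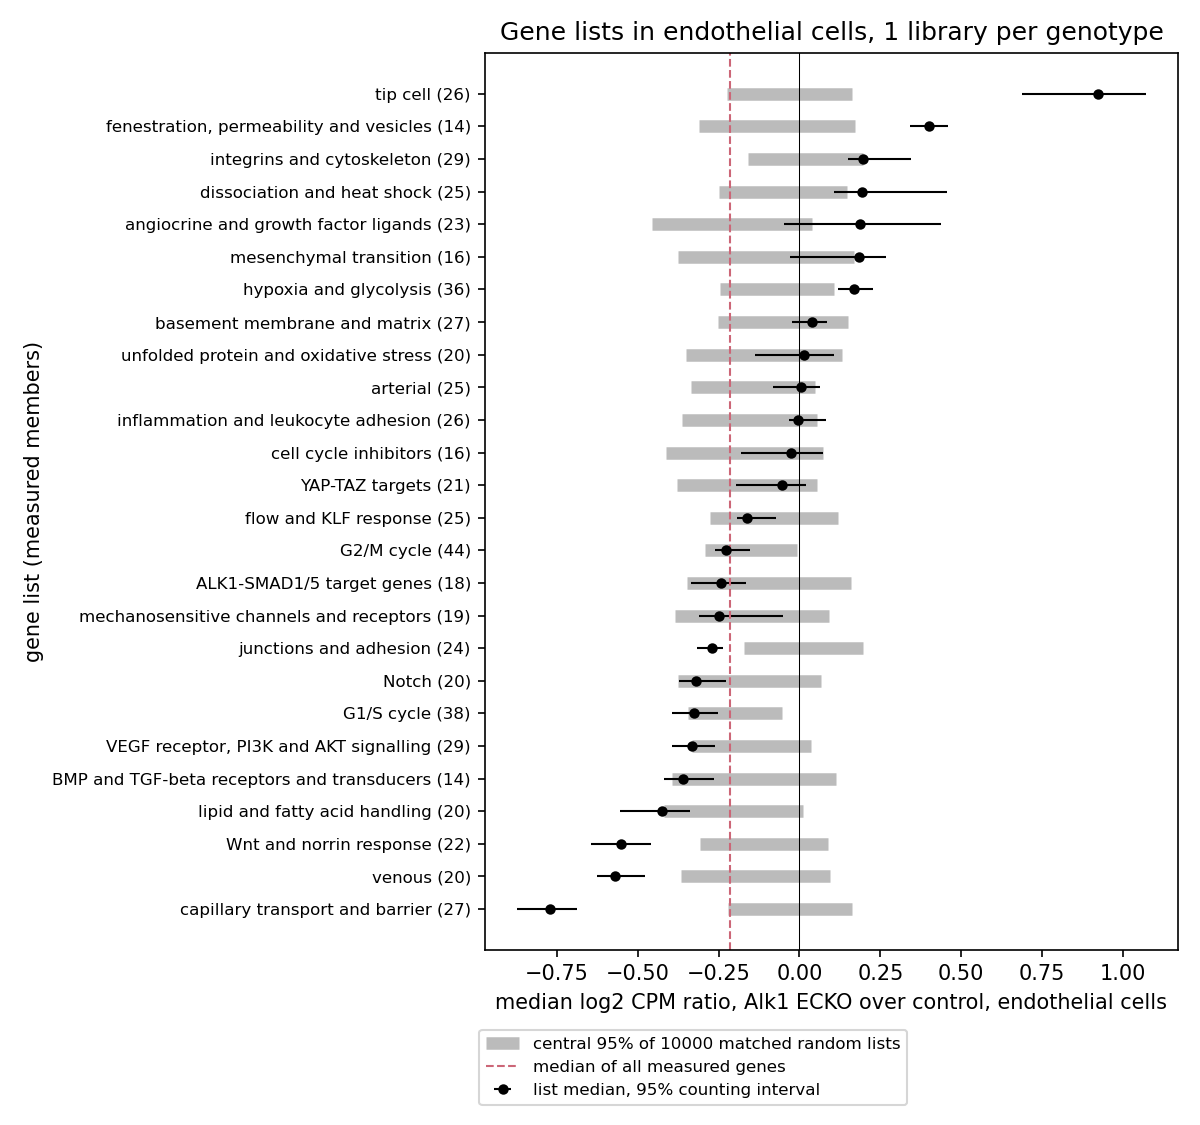
Median log2 CPM ratio (Alk1 ECKO over control) of the gene lists in endothelial cells, without the sex-linked list and the lists of genes and transcripts of other cell types, with 95% counting intervals, beside the central 95% of 10000 matched random lists and the median of all measured genes (dashed, -0.21). The tip cell list (0.92) and the barrier list (-0.77) are the highest and lowest of the lists drawn.

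The tip cell and barrier differences were also present within single endothelial clusters. The clusters compared held most of the endothelial cells used above, so they are no separate repeat. Cluster 4 held 188 control and 472 Alk1 ECKO cells and was led by Slc7a1, Cd93, Apod and Mfsd2a. Cluster 7 held 105 and 338 cells and was led by Apln and Plxnd1. Their tip cell medians, relative to all genes, were 0.95 (0.83 to 1.30) and 0.75 (0.65 to 0.87). Their barrier medians were -0.40 (-0.55 to -0.33) and -0.59 (-0.64 to -0.34), and their Wnt and norrin medians -0.38 and -0.22. Sub-cluster 6 (54 and 68 cells, led by replication histone genes), the only sub-cluster with at least 50 cells of both libraries, gave 0.42 for tip cell, -0.26 for barrier and -0.20 for Wnt and norrin genes. It was drawn from the same endothelial cells as the clusters and overlaps them, so it is no separate repeat. On the same relative scale Id3 was lower in cluster 4 (-0.90), cluster 7 (-0.83) and sub-cluster 6 (-0.50). Piezo1 was lower in cluster 7 (-0.32, -0.51 to -0.14) and sub-cluster 6 (-0.50, -0.83 to -0.17), and its interval included 0 in cluster 4 (-0.08, -0.27 to 0.11). Esm1 was higher in each (3.01, 1.56 and 0.60), whereas Angpt2, higher in cluster 4 (3.25) and cluster 7 (1.98), was at 0.42 (-0.03 to 0.87) in sub-cluster 6.

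G1/S genes differed in direction between these overlapping sets of cells. The share of cycling cells inside each cluster was not compared, so a different mix of them is not excluded. In cluster 4 the G1/S and G2/M medians relative to all genes were 0.43 (0.28 to 0.54) and 0.57 (0.39 to 0.75), and in sub-cluster 6 they were 0.28 and 0.34, against -0.17 (-0.27 to -0.10) and 0.03 (-0.0043 to 0.11) in cluster 7. Other lists in clusters 4 and 7 had relative medians of -0.43 and -0.23 for venous, 0.13 and 0.16 for arterial, 0.66 and 0.49 for fenestration, 0.06 and -0.03 for SMAD target, 0.00 and -0.07 for mechanosensitive, -0.02 and 0.13 for flow and -0.17 and -0.17 for VEGF receptor genes. In sub-cluster 6 the same lists were at -0.34, 0.13, 0.44, -0.13, -0.20 (-0.34 to -0.10), 0.00 and -0.28, in that order. Clusters 16 (8 control and 194 Alk1 ECKO cells) and 18 (5 and 166 cells, led by Esm1 and Angpt2) held too few control cells to compare. The choice of clusters 4 and 7 was made after the cell numbers were known, and differences in cluster sizes are not read as differences in cell states because the clusters were built partly on the genes that differed.

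Cell classes outside the endothelium, where the Cdh5 promoter is not active, were compared in the same way where both libraries held at least 100 cells. Hddc3 and AY036118, given above, were among the highest and lowest genes in both. In Müller glia or late progenitors of the Alk1 ECKO library the lactate exporter gene Slc16a3 (81.6 against 26.4 CPM, 1.63, 1.19 to 2.05), the metallothionein gene Mt1 (603 against 224 CPM, 1.43, 1.28 to 1.58), Klf4 (1.67) and Car3 (1.49) were higher. Snhg5 (-2.58), Snhg16 (-2.20), Mtmr4 (-2.40) and Rag1 (-2.17) were lower there, and 24 of 33 measured G1/S genes were lower (median -0.61, percentile 0.05). In rods Tshz2 (162 against 45.5 CPM, 1.83, 1.57 to 2.09), the hypoxia-inducible Ankrd37 (84.0 against 27.4 CPM, 1.62), Snx8 (1.59) and Flywch2 (1.45) were higher and Rnf121 (-2.89), Heatr5b (-2.29), Snap23 (-2.26) and Moxd1 (-2.25) lower.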

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

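Both tests in this part were chosen after the result had been seen.

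Barcodes in 5 set-aside clusters, which enter no comparison of cell classes, made up a higher share of the Alk1 ECKO than of the control library, beyond their exact Clopper-Pearson intervals. Cluster 2, led by Hbb-bs, Gpihbp1 and Hba-a1, held 1188 Alk1 ECKO and 0 control barcodes with a median of 1853.5 UMIs. Cluster 20, led by Hmox1, Lgals3 and Cd68, held 129 against 23 barcodes, cluster 25, led by Bvht, Ctla2a and Foxq1, 97 against 7, and cluster 33, led by Crhbp and Optc, 18 against 4. Cluster 26, with mural and endothelial markers together and a median of 59770 UMIs in Alk1 ECKO, held 99 against 4.

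The low mitochondrial share of cluster 2 may come from free RNA or cell fragments in droplets. After thinning to 1000 UMIs, 84.6% of its 1188 barcodes (82.4 to 86.6) held UMIs of at least 2 of the microglial, mural and photoreceptor lists, against 2.22% of 1170 endothelial cells (1.46 to 3.24), a ratio of 38.1, which goes with that explanation. The nuclear transcript Malat1 was at 838 against 8178 CPM, a ratio of 0.102 (0.0986 to 0.107), which argues against intact endothelial cells. C1qa was at 740 against 2.84 CPM and Hbb-bs at 1634 against 195 CPM. Whether the genotype plays a part was not tested, and where the RNA came from stays open.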

How the results depend on the processing

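Alternatives on low-mitochondrial and mixed barcodes, on the MHC class II and mural-led sub-clusters and on cells of over 50000 UMIs were chosen after seeing the data, as was giving list medians and log2 ratios relative to the median of all measured genes. That median was -0.21, but -0.01 under TMM scaling, -0.05 with the mean of per-cell CPM, -0.09 with equal sub-cluster makeup, -0.10 without cells of over 50000 UMIs and -0.12 after thinning. On the relative scale used below TMM scaling cannot change a value, since it shifts all ratios alike. Under every other alternative run tip cell genes stayed higher in Alk1 ECKO on that scale (0.68 to 1.32), as did fenestration genes (0.30 to 0.70). Barrier (-0.63 to -0.16) and venous genes (-0.39 to -0.22) stayed lower. Wnt genes ranged from -0.44 to -0.06 and Piezo1 from -0.28 to -0.05, and no interval was computed for the values nearest 0, so a direction there is not shown. Of the values that answer a comparison, 165 moved within their counting intervals, 40 moved further and 7 reversed, and of the others 612, 206 and 15. Reversed means that a value whose counting interval excludes 0 changed sign. SMAD target (-0.03), mechanosensitive (-0.03) and G2/M medians (-0.01) and that of the sex-linked list, with intervals that include 0, changed sign too under some alternatives and are not counted as reversed. For each moved or reversed value below the cause was not tested.

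With cells thinned to one depth the values were 0.097 for SMAD target, 0.095 for Notch, 0.13 for G1/S (reversed, as was Notch), 0.082 for G2/M, 0.22 for mechanosensitive (these and SMAD target with a changed sign), 0.46 for arterial, -0.44 for barrier, 1.32 for tip cell and -0.23 for venous genes, and 0.16 for Acvrl1. With cycling cells left out, YAP-TAZ (-0.18), cycle inhibitor (-0.12), G1/S (0.24), VEGF receptor (0.0013) and arterial genes (-0.51) and erythroid (-1.39) and mural transcripts (-0.52) reversed, while SMAD target (-0.33), barrier (-0.45) and flow genes (0.017) and Acvrl1 (0.070) moved. With equal sub-cluster makeup, BMP receptor (0.019), Notch (0.032) and junction genes (0.036) reversed, and SMAD target (0.095), G2/M (-0.25), VEGF receptor (-0.045), barrier (-0.16), tip cell (0.68) and venous genes (-0.25) and Piezo1 (-0.053) moved. With the mean of per-cell CPM, Notch (0.29), junction (0.075), G1/S (0.072) and VEGF receptor genes (0.027) reversed, and SMAD target (0.19), arterial (0.49) and barrier genes (-0.41) moved.

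Under the stricter cell filter SMAD target genes were at 0.097, G1/S at -0.25, G2/M at -0.19 and arterial at 0.39, and the endothelial share was 37.9% in Alk1 ECKO and 4.82% in control. The looser filter gave -0.051 for G2/M and an Alk1 ECKO share of 24.5%. Without cells of over 50000 UMIs, Notch genes (0.11) and erythroid transcripts (-0.21) reversed, and G2/M (-0.085), VEGF receptor (-0.024), barrier (-0.41) and venous genes (-0.22) moved. Without the MHC class II sub-cluster arterial genes reversed (-0.037) and SMAD target genes were at -0.21. Adding low-mitochondrial barcodes reversed photoreceptor transcripts (0.52), moved VEGF receptor genes to -0.18 and gave an Alk1 ECKO share of 60.0%, and leaving them out of the retained cells one of 44.0%. Free RNA subtraction put microglial transcripts at -1.67, which is counted as reversed although it is the floor value where no counts are left. Members with at least 1 UMI gave -0.014 for YAP-TAZ (reversed) and -0.16 for SMAD target genes, and adding mixed barcodes gave -0.074 for G2/M. Control held 11 mural cells and 52 microglia or macrophages, which limits the comparisons in those classes.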

Other observations

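The tests of explanations in this part were chosen after the result had been seen, except that of B lymphocyte RNA, while the gene lists were fixed beforehand. Of 24 junction and adhesion genes 10 were lower and 1 higher (median log2 ratio -0.27, -0.32 to -0.24, percentile 0.31 of random lists), with N-cadherin (Cdh2) at 201 against 406 CPM (-1.02), the tight junction gene Ocln at -0.77, Jam2 at -0.62 and Rap1a at 0.34, but relative to all genes the median was -0.06, and 0.075 with the mean of per-cell CPM. Cdh2 was also lower in rods (-0.65). Of 20 lipid handling genes 13 were lower and 1 higher (-0.42, -0.55 to -0.34, percentile 2.12), with Apoe at -1.56, the cholesterol exporter Abca1 at -1.14, Scd2 at -1.04 and the lipase anchor Gpihbp1 at 1.66. Relative to all genes the lipid median was -0.21, and -0.06 after thinning. Integrin and cytoskeleton genes were higher in 14 and lower in 3 of 29 (0.20, 0.15 to 0.34, percentile 97.6), led by the myosin light chain Myl9 (58.7 against 4.83 CPM, 3.60), with Actb at 0.71 and Itga2 at -0.89. Relative to all genes this median was 0.41, and 0.20 with equal sub-cluster makeup, and in sub-cluster 6 members went both ways (8 higher, 7 lower, percentile 61.2). Among 23 angiocrine ligands 11 were higher and 7 lower (0.19, percentile 99.9), with Igf1 at 1.83, Apln at 1.42, Slit2 at -0.92 and Ccl2 at -3.42. Their relative median was 0.40, with 0.19 when cycling cells were left out and 0.77 with equal sub-cluster makeup. Of 16 mesenchymal transition genes 6 were higher and 5 lower (0.18, percentile 98.0), with Tagln at 2.52, Ccn2 at 0.86 and Zeb2 at -0.97. Their relative median was 0.40, but 0.11 after thinning. Mural contractile genes (0.87, 6 of 9 higher) include Myl9 and Tagln, which pericytes express as well, and mural transcripts in this class were higher in Alk1 ECKO. The relative median of the contractile list, 1.09, came to 0.35 without cycling cells, 0.49 after thinning and 2.28 with mixed barcodes added.

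Basement membrane genes had a median of 0.04 (8 of 27 higher, 5 lower), with Col18a1 at -1.09 and Emilin1 at 0.73. Inflammation genes were at -0.01 (7 of 26 higher, 8 lower), but at 0.21 relative to all genes, with Cd74 at 4.0 (2.82 without sub-cluster 3, which was rich in MHC class II transcripts), Socs3 at 1.11, Sele at -1.79 and Cxcl10 at -1.91. Cycle inhibitors were at -0.03 (5 of 16 higher, 6 lower), but at 0.19 relative to all genes. Among them the p21 gene Cdkn1a was higher (173 against 73.6 CPM, 1.23) and Rb1 lower (-0.93). YAP-TAZ targets were at -0.05 (3 of 21 higher, 9 lower), but at 0.16 relative to all genes, with Myof at -1.05 and Yap1 at -0.71. Unfolded protein and oxidative stress genes were at 0.01, microglial activation genes at 0.30 and glial reactivity genes at 0.30 in endothelial cells. The microglial activation median, 0.51 relative to all genes, was 0.018 after thinning, 0.12 after free RNA was subtracted and 1.87 with low-mitochondrial barcodes added, and microglial transcripts in this class were higher too. In microglia or macrophages 11 of 15 unfolded protein genes were lower and 0 higher (-0.57, -0.69 to -0.48), as were 11 of 15 flow and KLF response genes (-0.61, -0.69 to -0.40), over 52 control cells. In mural cells 40 of 41 G2/M genes were higher (2.32, 2.16 to 2.63), 24 of 35 G1/S genes were higher (0.67) and 9 of 13 contractile genes were lower (-0.71), a comparison against 11 control cells only.

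Tip cell genes were higher and barrier genes lower in endothelial cells of the Alk1 ECKO library. In whichever of clusters 4 and 7 lay nearer 0, the relative median was 0.748 (0.646 to 0.873) for tip cell and -0.401 (-0.546 to -0.329) for barrier genes. This argues against a different mix of these 2 clusters as the whole cause. It cannot speak against another mix of cell states inside each cluster, which may differ between the libraries. Equal sub-cluster makeup, over 6 of the 10 sub-clusters, brought the barrier median to -0.16. A difference shared by all cell classes stays open for the members also measured in Müller glia or late progenitors: 17 barrier genes were as low there (-0.263, -0.55 to -0.0035) as in endothelial cells (-0.234), and 7 tip cell genes were at 0.339 (-0.31 to 0.429) against 0.494. These medians have the size that a shared difference needs, although both intervals also reach values too small for it. Loss of Alk1 stays open as a cause and was not tested, since each genotype had 1 library.

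Sub-cluster 3 of the endothelial cells held 182 Alk1 ECKO and 2 control cells with a median of 2388.5 UMIs in Alk1 ECKO and was led by Mgp (1938 CPM) and the MHC class II chain Cd74 (329 CPM). In its Alk1 ECKO cells the 4 Y-linked genes summed to 11.4 CPM (4.93 to 22.5), against 74.4 to 219 in those of the 9 other sub-clusters. Xist was at 685 CPM there, against 53.2 to 154 in Alk1 ECKO cells of the others. Over both libraries Xist reached 316 CPM in sub-cluster 4. The cells of sub-cluster 3 may thus come from a source with another sex makeup than the other endothelial cells of the Alk1 ECKO library. B lymphocyte RNA or attached B lymphocytes as the origin of the MHC class II transcripts are argued against by 0 Igkc and Cd79a UMIs, where the 232 Cd74 UMIs would bring 408 (ratio 0, upper bound 0.00905). Microglia or macrophages as their origin were not tested. Relative to all genes the median of microglial transcripts was 2.33 over all endothelial cells and 1.71 without this sub-cluster. Which animal or vessel bed these cells came from stays open, as does an effect of the genotype, which was not tested.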
